A study of Mus musculus with 15 samples.

How the data were processed

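Gene expression was measured on Affymetrix Mouse Gene 1.0 ST arrays, a platform whose probe sets cover the length of each transcript, in 15 samples of bone marrow progenitors from female C57BL/6 mice. Per the labels' protocols, marrow was enriched for cKit-positive cells, and pre-granulocyte-macrophage progenitors (preGMs) and granulocyte-macrophage progenitors (GMPs) were sorted by flow cytometry. RNA was extracted with a kit for small samples, amplified as cDNA from 20 ng and biotin-labelled. The values the authors deposited are log2 expression values, and the submitters' processing notes name affy and RMA, which corrects background, normalizes arrays to common quantiles and summarises the probes of a set. The versions of both, and any filter applied, are not given in the sources used here. The values of the deposited table ran from about 2 to about 14, and the median log2 value per array lay between 6.03 and 6.23. Arrays have no read depth, and their number (3 per group) limits the precision.

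The table held 34760 probe sets. The platform annotation gave 1 gene symbol to 21640 of them, several to 1321, and the other 11799 are unnamed here. Of the probe sets with 1 symbol, 21553 matched the mouse RefSeq gene table (assembly GRCm38.p6, used for names only) by Entrez ID, and 0 symbols were updated. The 19937 genes tested were represented by their probe set, and by the one with the highest mean over the 15 arrays for the 954 genes with more than 1. Among named genes, another probe set of the gene had the opposite sign for Ywhaz against the GMP control and for Cycs between the mutants. Dim probe sets were not filtered out.

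Groups came from the labels: 5 groups of 3 arrays. The labels number each animal, and the fl/p30 preGMs and GMPs came from the same 3 animals (168, 986 and 988), while the other groups came from separate ones. A linear model with 5 group means over all 15 arrays was fitted with limma 3.58.1 (R 4.3.3), with eBayes moderation without trend, 10 residual and 4.24 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes within each of 7 comparisons, and a gene was called at an adjusted p under 0.05. Unless stated otherwise, adjusted p-values are limma's, differences are log2 differences, and ± is their standard error (SE). All groups sharing 1 estimate of the spread lends the comparisons degrees of freedom, and it gives less exact p-values where groups differ in spread. The root mean square of the within-group SDs was 0.319 in GMP fl/+, 0.269 in GMP fl/p30, 0.211 in preGM fl/p30, 0.195 in GMP fl/BRM2 and 0.165 in preGM +/+. The shared estimate thus tends to give too low p-values for the GMP mutants against GMP fl/+. Between the preGM groups it tends to give too high ones.

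Before the data were examined, the test, its samples, the alternatives, the named genes and 25 gene lists were fixed. Of 480 list entries, 434 were measured. The lists covered cell types (primary granule, secondary granule and neutrophil, monocyte and dendritic, stem and multipotent progenitor, megakaryocyte, erythroid, mast with basophil and eosinophil, B lymphoid, T and NK, mature macrophage, stroma and endothelium), the sort gate, the C/EBP family, the Hoxa cluster and leukaemia-linked genes, cytokine receptors, cell cycle phases (E2F and S, G2 and M), Myc and ribosome biogenesis, interferon response, immediate early and heat shock genes, cholesterol synthesis, oxidative phosphorylation, glycolysis and hypoxia, p53 targets, and housekeeping genes. Each list was tested in each comparison with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, giving 175 tests. Camera with a correlation estimated from the residuals and fry (direction of a list by itself) stand beside it. In each of the 82 lists called by camera, the median, the mean and the test had the same sign.

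Named genes were Cebpa, the 10 highest and 10 lowest called genes without overlap between the arrays of the 2 groups for each mutant against its control (5 and 5 for the other comparisons), up to 4 called members of each list, or up to 2 members where none was called, and the sort gate. Symbols of clones and predicted genes were left out. A few more list members and genes are named after their values were seen, in the shared calls of the closing part and for P2rx7 in other comparisons.

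Pairing was checked by correlating, across genes, the deviations of same-animal arrays from their group means. The correlations were 0.334, 0.32 and 0.116 for the 3 fl/p30 animals. For the last of these the array of another animal gave a higher value (0.154). The 2 fl/p30 groups are paired by their animal numbers, which this check bears out only in part. Fits with the animal as a block are given where they moved a count by over 1.5 times. The replicate numbers of the other groups carried no shared animal.

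Tests were checked on simulated data with the arrays' means and gene-wise spread, 19937 genes and, per comparison, 100 genes changed by each of 2 sizes. A log2 change of 1 was recovered for 86% of changed genes in GMP fl/p30 against GMP fl/+, 83% in GMP fl/BRM2 against GMP fl/+, 80% in preGM fl/p30 against preGM +/+, 80% between the mutants and 56% in the interaction. The simulation drew independent normal noise with no difference in quality between arrays. Alternatives included other moderation, other handling of several probe sets per gene, all probe sets, a filter on dim genes, fewer arrays in the fit, median centring, quantile normalization, array weights, a fold threshold, blocks and leaving out each array in turn. One was added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.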

Results

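The series profiled 2 consecutive stages of myeloid progenitors from mice with mutant Cebpa, the gene of the transcription factor C/EBPα, in a search for genes deregulated before leukaemia arises. Cells were taken 3 weeks after conditional knockout. PreGMs were sorted as Lin−, Sca1−, cKit+, CD150−, CD41−, FcgRII− and Endoglin−, and the more mature GMPs as Lin−, Sca1−, cKit+, CD150−, CD41− and FcgRII+. The p30 allele makes only the shorter C/EBPα isoform, which lacks the N-terminal transactivation part, and the BRM2 allele carries a mutated basic region that impairs repression of E2F. There were 5 groups of 3 arrays: preGM +/+, preGM fl/p30, GMP fl/+, GMP fl/BRM2 and GMP fl/p30. The preGM control carried 2 normal alleles and the GMP control 1 normal and 1 floxed allele, so the controls of the 2 stages differed in genotype.

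Where the lower group of a comparison lay below the array medians (6.03 to 6.23), near the background, the difference is given in log2 without a fold, and it may understate the change. The arrays of a group were not equally alike. Levels below are mean deviations from each gene's mean over the 15 arrays (log2). The 54 small nucleolar RNA genes, a set chosen after the data were seen, lay at -0.42 in GMP fl/+ replicate 1, at 0.85 and 1.23 in replicates 2 and 3, and at -1.21 in GMP fl/p30 replicate 1. Both arrays of the first fl/p30 animal had low mitotic genes. The G2 and M phase list lay at -0.96 in GMP fl/p30 replicate 1 and -0.55 in preGM fl/p30 replicate 1. The secondary granule list lay at -0.87, -0.54 and 0.48 in the 3 GMP fl/p30 arrays. The B lymphoid list stood at 1.62 in preGM +/+ replicate 3, against 0.16 and 0.18 in the other preGM +/+ arrays.

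The level of Cebpa (probe set 10552140) was 8.58, 8.61 and 8.53 (log2) in the preGM +/+ arrays and 9.28, 8.90 and 9.10 in preGM fl/p30. In GMPs it was 8.70, 8.10 and 8.34 in fl/+, 8.59, 8.48 and 8.86 in fl/BRM2, and 8.68, 9.22 and 9.31 in fl/p30. Where its probes lie relative to the deleted and mutated parts is not known here, so these levels check nothing about the deletion. Cebpa was higher in GMP fl/p30 than in GMP fl/+ by 0.69 ± 0.18 (adjusted p = 0.0367). That call was lost without GMP fl/+ replicate 2 or 3 or GMP fl/p30 replicate 2 or 3 (adjusted p up to 0.15). The differences of 0.27 (GMP fl/BRM2 against fl/+, adjusted p = 0.562) and 0.52 (preGM fl/p30 against +/+, adjusted p = 0.204) did not pass.

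What the p30 allele changed in GMPs was asked by comparing GMP fl/p30 with GMP fl/+. Scin, the gene of an actin-severing protein, rose 36.9-fold (log2 difference 5.21 ± 0.23, n = 3 arrays per group), and Gzmb, the granzyme B of cytotoxic lymphocytes, rose 24.8-fold (4.63 ± 0.27). Tox, a factor of T-cell development, rose 17.1-fold, Il6, an inflammatory cytokine, by 4.33 and the sialyltransferase gene St8sia6 by 3.97. Prkcq and Prkca, which encode protein kinase C isoforms, rose by 3.65 and 3.29, with Ctla2a (3.42), Plxdc2 (3.28) and the carbonic anhydrase gene Car1 (3.26). S100a8 and S100a9, the subunits of the neutrophil protein calprotectin, fell 18.9-fold and 13.4-fold (-4.24 ± 1.08 and -3.74 ± 0.94). F13a1, the A chain of coagulation factor XIII in monocytic cells, fell 8.11-fold, Ppic 7.21-fold, the ficolin gene Fcnb 5.32-fold and Tmem150b 5.27-fold, and the cytokine gene Tslp fell by 2.35. Prg2, an eosinophil granule protein gene, fell by 3.45, Snora7a by 2.33 and Prom1 by 2.23. Without GMP fl/p30 replicate 1 or 3 the differences were -2.95 or -5.80 for S100a8, -2.78 or -5.03 for S100a9 and -2.45 or -4.31 for Prg2. Without replicate 3 they were -3.75 for F13a1 and -3.05 for Fcnb, and without replicate 1 Snora7a was at -1.68. Snora7a ranged from -2.91 to -1.17 over all settings. It is 1 of the 54 small nucleolar RNA genes, which lay at -0.42, 0.85 and 1.23 in the GMP fl/+ arrays, so its fall may reflect differences between arrays. Tslp was at -3.04 without GMP fl/+ replicate 1 and at -0.97 against that array alone, where it was not called. Of the genes in this paragraph, S100a8 and S100a9 lost the call without GMP fl/+ replicate 2 or 3 or GMP fl/p30 replicate 1 or 2 (adjusted p up to 0.143), Prg2 without the same arrays (up to 0.0939), Snora7a without GMP fl/+ replicate 2 or 3 or GMP fl/p30 replicate 1 (up to 0.109) and Prom1 without GMP fl/p30 replicate 1 (0.0534).

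Of 18 measured erythroid genes, 10 rose, 0 fell and 8 did not pass (14 rose when adjusted over the list alone). Car1 and Car2, the carbonic anhydrases of red cells, rose by 3.26 and 2.16, the blood group gene Icam4 by 1.28 and the erythroid factor Gata1 by 1.06. Camera called the list (adjusted p = 3.3e-12), but not with an estimated correlation (adjusted p = 0.166). The T and NK list had 5 of 15 genes higher and 0 lower (7 higher adjusted over the list alone), among them the chemokine gene Ccl5 (2.29), the T-cell adaptor Lat (2.04) and Cd7 (0.98), and its call held with an estimated correlation (adjusted p = 0.018). The other 2 of the 5, Cd3g and Klrd1, kept their calls in 1 of 6 leave-outs, without GMP fl/+ replicate 1 and 2 respectively (adjusted p up to 0.0799 and 0.171). Of 13 megakaryocyte genes, Itga2b, Itgb3 and Nfe2 rose and 10 did not pass (4 rose adjusted over the list alone; adjusted p = 0.248 with an estimated correlation). Itga2b and Nfe2 lost the call without GMP fl/p30 replicate 1 or 2, and Itgb3 without those or GMP fl/+ replicate 2 (adjusted p up to 0.106, 0.0698 and 0.0799).

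Of 20 secondary granule and neutrophil genes, 7 fell, 1 rose and 12 did not pass (11 fell and 1 rose adjusted over the list alone). Of the 8 that passed, Fcnb kept its call whichever of the 6 arrays was left out, and the other 7 lost it without GMP fl/p30 replicate 2 (adjusted p up to 0.191, for Ngp). Of those, all but Padi4 lost it also without GMP fl/p30 replicate 1, Ngp without GMP fl/+ replicate 1 or 2, S100a8 and S100a9 without 2 or 3, Padi4 and Abca13 without 3, and Cd177 without any 1 of the 6. The fall of the list (camera, adjusted p = 7.48e-05) was lost with an estimated correlation (adjusted p = 0.326), and within GMP fl/p30 the level of the list ranged from -0.87 to 0.48. None of the 14 primary granule genes passed (0 also adjusted over the list alone), with Elane, the neutrophil elastase, at -2.52 ± 0.86. That list was called lower (adjusted p = 0.0211), but not with an estimated correlation (adjusted p = 0.695), nor without GMP fl/+ replicate 1 (0.462) or GMP fl/p30 replicate 1 (0.577). Among 17 mast cell, basophil and eosinophil genes, 5 rose and 4 fell (8 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.25). The mast cell carboxypeptidase Cpa3 (3.09), the monoamine transporter Slc18a2 (2.34), Gata2 (1.93), Cma1 and Csrp3 rose, while the histidine decarboxylase Hdc (-2.21; -2.80 without GMP fl/p30 replicate 3), Prss34 (-1.51), Mcpt8 and Prg2 fell.

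Stem and multipotent progenitor genes were called higher as a list (adjusted p = 0.0476), which was lost with an estimated correlation (adjusted p = 0.657) and without GMP fl/+ replicate 1 (0.199) or 2 (0.0802) or GMP fl/p30 replicate 1 (0.0766) or 2 (0.0949). It was also lost, at adjusted p of 0.0501 to 0.0663, without preGM +/+ replicate 1 or 3, preGM fl/p30 replicate 2 or 3 or GMP fl/BRM2 replicate 3. Of the 22 genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone), with the growth factor gene Angpt1 higher by 3.25, Gata2 by 1.93 and the polycomb gene Bmi1 by 1.02. Of 20 monocyte and dendritic genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone). Id2, an inhibitor of helix-loop-helix factors, rose by 2.73, and Irf8, a factor of monocyte and dendritic cell development, fell by 1.72. Of 15 cytokine receptor genes, 3 rose and 3 fell (3 and 5 adjusted over the list alone), led by Csf2rb2 (2.31). The G-CSF receptor gene Csf3r fell by 1.32, without the call when GMP fl/+ replicate 2 or 3 or GMP fl/p30 replicate 1 or 2 was left out (adjusted p up to 0.139). Neither of these lists was called (adjusted p = 0.309 and 0.751). Single arrays moved these counts. The receptors lower were 1 without GMP fl/+ replicate 2, 0 without GMP fl/+ replicate 3 or GMP fl/p30 replicate 1 or 2, and 5 without GMP fl/p30 replicate 3, and those higher 1 without GMP fl/p30 replicate 1. The monocyte and dendritic genes lower were 6 without GMP fl/p30 replicate 3, and those higher 1 without GMP fl/+ replicate 2 or GMP fl/p30 replicate 1. The stem cell genes lower were 1 without GMP fl/+ replicate 2 or 3 or GMP fl/p30 replicate 1 or 3.

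Interferon response genes rose in 5 of 22 cases and fell in 0 (8 and 1 adjusted over the list alone), with Rtp4 at 2.09 and Usp18 at 1.66 (adjusted p = 0.474 with an estimated correlation). The other 3, Rsad2, Zbp1 and Trim30a, lost the call in some leave-outs (adjusted p up to 0.16), so that 3 genes rose without GMP fl/+ replicate 2 and 2 without GMP fl/+ replicate 3 or GMP fl/p30 replicate 1 or 2. Of 18 cholesterol synthesis genes, Fdft1 and Srebf2 rose (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.365 with an estimated correlation). Both lost the call without GMP fl/+ replicate 2 or 3 or GMP fl/p30 replicate 1 or 2 (adjusted p up to 0.161 and 0.0883), 9 rose without GMP fl/+ replicate 1, and the level of the list was 0.19, -0.82 and -0.37 in the 3 GMP fl/+ arrays. The p53 targets Trp53inp1 (2.52) and Perp (1.47) rose, with 14 of 16 targets not passing (2 rose adjusted over the list alone; adjusted p = 0.162 with an estimated correlation; 0.0509 with the preset one without GMP fl/+ replicate 1, where 4 rose). The G2 and M phase list was called lower with 0 of 24 genes passing (0 adjusted over the list alone; camera, adjusted p = 0.000236). That call was absent with an estimated correlation (adjusted p = 0.695), without GMP fl/p30 replicate 1 (0.398) and without GMP fl/+ replicate 1 (0.145). Of 29 E2F and S phase genes, Tk1 and Cdc45 fell (2 also adjusted over the list alone), and the list's call was likewise lost with an estimated correlation (adjusted p = 0.695), without GMP fl/p30 replicate 1 (0.975) and without GMP fl/+ replicate 1 (0.53). Tk1 and Cdc45 lost their calls without GMP fl/+ replicate 2 or 3 or GMP fl/p30 replicate 1 or 2 (adjusted p up to 0.128 and 0.127), and 6 fell without GMP fl/p30 replicate 3.

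Of the lists that remain, oxidative phosphorylation was called higher with 0 of 25 genes passing, also adjusted over the list alone (adjusted p = 0.0151; 0.695 with an estimated correlation), and it was not called without GMP fl/+ replicate 2 (0.723) or 3 (0.169) or GMP fl/p30 replicate 3 (0.186). The other lists were not called. The C/EBP family had 2 of 6 genes higher, Cebpa and Cebpg, and Cebpd lower, all 3 without the call when GMP fl/p30 replicate 2 was left out. Cebpg and Cebpd lost it also without GMP fl/p30 replicate 1 and Cebpd without GMP fl/+ replicate 2 (adjusted p up to 0.0632 and 0.0867). The B lymphoid list had 3 of 17 higher, including Dntt, the template-independent DNA polymerase of lymphocyte precursors (1.45). Of the others, stroma and endothelium had 1 of 13 genes higher (Pdgfrb), immediate early and heat shock 1 of 18 higher and 1 lower, glycolysis and hypoxia 1 of 19 lower, the Hoxa and leukaemia-linked list 1 of 20 higher, and mature macrophage (15 genes), Myc and ribosome biogenesis (23) and housekeeping (8) none either way. With single arrays left out these counts of 1 fell to 0 or rose to at most 3 in the immediate early, glycolysis and Hoxa lists. Adjusted over the list alone, the counts higher and lower were 2 and 2 in the C/EBP family, 3 and 0 in the Hoxa list, and as over all genes in the others. Of the 7 sort gate genes, a list that was not called (adjusted p = 0.413), Itga2b, which encodes CD41, was 1.05 higher (2 higher and 1 lower adjusted over the list alone), while Fcgr3 differed by 0.00 ± 0.20 and Fcgr2b by -1.07 ± 0.30 (adjusted p = 0.051).

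In this comparison limma called 1209 of 19937 genes, 935 higher and 274 lower, 3989 had an unadjusted p under 0.05, and the arrays of the groups did not overlap for 17.4% of all genes, where chance gives 10%. The count was 3078, 702 and 743 without GMP fl/+ replicates 1, 2 and 3, and 537 and 600 without GMP fl/p30 replicates 1 and 2. It was 311 with only GMP fl/+ replicate 1 as control (chosen after the data were seen), 172 in a fit of the 6 arrays alone, 4063 with array weights and 482 with an absolute log2 difference of at least 1. Of 65 named calls, 37 held whichever array was left out.

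**Figure D1:**
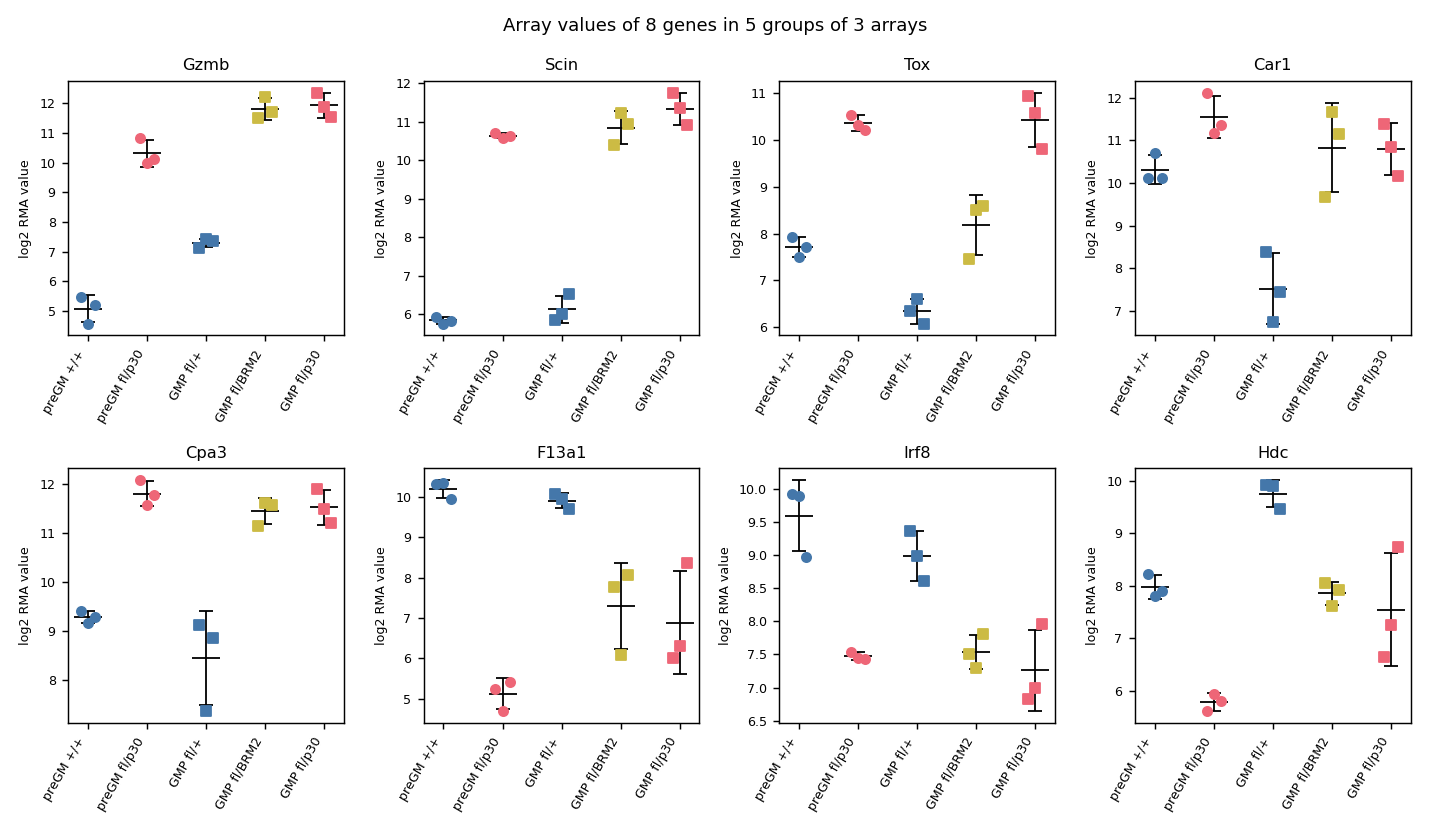
Levels (log2 RMA value, y axis) of 8 genes in the 5 groups (x axis), with 1 point per array and a black line at the mean with bars of 1 SD (n = 3). Gzmb and Scin lie at 9.997 or more in every mutant array and at 7.414 or less in every control array, while F13a1, Irf8 and Hdc are lower in the mutant groups of each stage.

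The BRM2 allele was compared with the same GMP control. Scin rose 26.3-fold (log2 difference 4.72 ± 0.23, n = 3 arrays per group), Gzmb 22.8-fold (4.51 ± 0.27), Car1 9.84-fold (3.30 ± 0.49) and Il6 by 4.07 ± 0.44. Plxdc2 (3.27), Ctla2a (3.16), the ubiquitin ligase gene Trim13 (3.15), St8sia6 (3.14), Prkcq (3.09) and Cpa3 (3.00) followed. Fcnb fell 7.06-fold and Fgd4 by 1.98. Stox2, with 2 probe sets of unequal change, was lower, at -2.26 in the brighter one, -0.07 in the other and -1.16 in their mean, which was called too. The glutathione transferase gene Mgst2 fell by 3.03, F13a1 by 2.60, Far2 by 2.40, the pyrin gene Mefv by 2.29, Tslp by 2.09 and Hdc by 1.90, and Ppic fell 4.01-fold. These 7 calls were lost without GMP fl/BRM2 replicate 2, and some without other arrays too. That held for Mgst2 and Tslp without GMP fl/+ replicate 2 or 3 or GMP fl/BRM2 replicate 3, Far2 without GMP fl/BRM2 replicate 3, F13a1 and Ppic without GMP fl/+ replicate 2, and Ppic without GMP fl/BRM2 replicate 1 (adjusted p up to 0.238 for Mgst2). Mgst2 was at -3.62 and -2.33 without GMP fl/BRM2 replicates 1 and 2, F13a1 at -1.99 without replicate 2, and Tslp at -2.78 without GMP fl/+ replicate 1 and at -0.72 against that array alone.

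Of 18 erythroid genes, 8 rose and 0 fell (15 rose adjusted over the list alone), with Car2 at 2.23, Icam4 at 1.47 and Gata1 at 1.20 (camera, adjusted p = 2.61e-17; adjusted p = 0.154 with an estimated correlation). The count was 5 without GMP fl/BRM2 replicate 2, where Ermap, Mns1 and Tspan8 lost the call; Ermap and Mns1 lost it also without GMP fl/+ replicate 3 and Ermap without GMP fl/BRM2 replicate 3 (adjusted p up to 0.174, 0.0857 and 0.0514). Mast cell, basophil and eosinophil genes rose in 5 of 17 cases (Cpa3, Slc18a2, Gata2, Cma1 and Csrp3) and fell in 2 (Hdc and Prss34), 8 and 5 adjusted over the list alone. The list was called higher (adjusted p = 0.0124; adjusted p = 0.154 with an estimated correlation; 0.0559 without GMP fl/+ replicate 1). Gp5, Itgb3 and Nfe2 rose among 13 megakaryocyte genes (4 rose adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), each losing the call without GMP fl/BRM2 replicate 2. Gp5 and Nfe2 lost it also without GMP fl/+ replicate 2 or 3 or GMP fl/BRM2 replicate 3 (adjusted p up to 0.253). Camp, Fcnb and Abca13 fell among 20 secondary granule genes (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.315 with an estimated correlation). Camp and Abca13 lost the call without GMP fl/+ replicate 2 or GMP fl/BRM2 replicate 2 or 3, Camp also without GMP fl/BRM2 replicate 1 and Abca13 without GMP fl/+ replicate 3 (up to 0.195 and 0.212). In the T and NK list Lat rose (1.86) and 14 of 15 genes did not pass (2 rose adjusted over the list alone), and the list was not called (adjusted p = 0.0588). Trp53inp1 (2.07) and Perp (1.47) rose among 16 p53 targets (2 adjusted over the list alone; 4 without GMP fl/+ replicate 1). Stem and multipotent progenitor genes rose in 3 of 22 cases, Angpt1 (2.92), Gata2 (1.77) and Sox4, and fell in 1, Hlf (-0.71), with 6 and 4 adjusted over the list alone. Of 15 receptors, Csf2rb2 (2.60) and Csf2rb (1.15) rose, and Csf3r (-1.35), Csf2ra (-1.21) and Il6ra fell (3 and 5 adjusted over the list alone). Among these, Angpt1, Gata2 and Csf2rb2 kept the call whichever array was left out, and the others lost it without GMP fl/BRM2 replicate 2 or 3. Sox4 lost it also without GMP fl/+ replicate 2, Il6ra without 3, Csf3r, Csf2ra, Hlf and Csf2rb without 2 or 3, and the last 2 without GMP fl/BRM2 replicate 1 (adjusted p up to 0.262, for Csf3r). None of 29 E2F and S phase genes passed (0 also adjusted over the list alone), and neither that list (adjusted p = 0.342) nor the G2 and M phase list (adjusted p = 0.429) was called. Among the lists called with the preset correlation, cholesterol synthesis (0.000226; 0 of 18 genes passing), oxidative phosphorylation (0.000799; 0 of 25) and the p53 targets (0.015) lost the call with an estimated one (adjusted p = 0.315, 0.684 and 0.154), oxidative phosphorylation also without GMP fl/+ replicate 2 (0.292) and the p53 targets without replicate 1 (0.0548). Of the other lists called, mature macrophage (0.015), interferon response (0.0195) and B lymphoid genes (0.0392) were higher and primary granule genes (0.0467) lower, none of them with an estimated correlation (adjusted p = 0.315, 0.684, 0.71 and 0.71). In these lists 0 of 15, 2 of 22 (Rsad2 and Rtp4), 1 of 17 (Dntt) and 0 of 14 genes passed. Adjusted over the list alone, the counts higher and lower were 3 and 0, 2 and 1, 1 and 0, and 0 and 0. Rsad2 lost the call without GMP fl/+ replicate 3 or GMP fl/BRM2 replicate 2 or 3 and Rtp4 without GMP fl/+ replicate 2 or GMP fl/BRM2 replicate 2 (adjusted p up to 0.147 and 0.0884). Each list lost the call without GMP fl/+ replicate 1 (0.0711, 0.0711, 0.181 and 0.666). Mature macrophage lost it also without GMP fl/BRM2 replicate 3 (0.135). Interferon response lost it also without GMP fl/+ replicate 2 (0.282) or GMP fl/BRM2 replicate 2 (0.255), and B lymphoid without GMP fl/+ replicate 3 (0.0744) or GMP fl/BRM2 replicate 2 (0.255). Primary granule lost it also without GMP fl/BRM2 replicate 2 (0.546) or, at 0.052 to 0.0615, any preGM +/+ array, preGM fl/p30 replicate 1 or 2 or GMP fl/p30 replicate 2.

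For BRM2, 505 genes were called, 377 higher and 128 lower, with 2985 at an unadjusted p under 0.05 and no overlap of the arrays for 15.2% of genes (chance 10%). The count was 2218, 276 and 315 without GMP fl/+ replicates 1, 2 and 3, and 134 and 211 without GMP fl/BRM2 replicates 2 and 3. It was 113 with only GMP fl/+ replicate 1 as control, 131 in a fit of the 6 arrays alone, 2187 with array weights, 277 over all probe sets and 274 with the fold threshold. Of 49 named calls, 24 held whichever array was left out.

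The 2 mutants were compared directly. Tox was 4.76-fold higher in GMP fl/p30 than in GMP fl/BRM2 (log2 difference 2.25 ± 0.30, 95% interval 1.61 to 2.89; adjusted p = 0.0482), with 3 of 3 arrays above all of the other group. It was the 1 gene called, 688 genes had an unadjusted p under 0.05, and arrays did not overlap for 8.3% of genes, under the 10% of chance. Several differences whose intervals excluded 0 did not pass: Cxcr2, a chemokine receptor gene of neutrophils, was at -3.00 (-4.01 to -2; adjusted p = 0.0997), Ccl5 at 1.57 (0.99 to 2.14) and Ms4a2, a chain of the mast cell IgE receptor, at -1.65 (-2.34 to -0.96). For Gzmb the difference was 0.12 (-0.47 to 0.71), for Il6 0.26 (-0.68 to 1.21) and for Car1 -0.04 (-1.08 to 1.01). The 95% interval lay within 1 either way for 19191 of 19937 genes, which bounds single differences and does not show that the alleles act alike. The T and NK list was higher in GMP fl/p30 (camera, adjusted p = 2.34e-10; 0.00301 with an estimated correlation), with 0 of 15 genes passing over all genes and 4 adjusted over the list alone (Ccl5, Cd7, Klrd1 and Cd3g). The G2 and M phase list was lower with 0 of 24 genes passing (adjusted p = 0.446 with an estimated correlation), and its level was -0.96 in GMP fl/p30 replicate 1 against -0.02 and 0.03 in the other 2. Lists of Myc and ribosome biogenesis (9.78e-05), E2F and S phase (0.0196) and mature macrophage genes (0.0388) were also called lower and interferon response higher (0.0101), none of them with an estimated correlation (adjusted p = 0.72, 0.899, 0.647 and 0.781). Without GMP fl/p30 replicate 1 the Myc call was lost (0.813) and the E2F list turned higher (0.07). The E2F call was also lost without GMP fl/BRM2 replicate 3 (0.2). The interferon call was lost without GMP fl/BRM2 replicate 1 (0.0926) or 3 (0.205) or GMP fl/p30 replicate 2 (0.44). The macrophage call was lost without GMP fl/BRM2 replicate 2 (0.169) or 3 (0.71), GMP fl/p30 replicate 1 (0.0629) or 2 (0.44), or preGM fl/p30 replicate 1 (0.0626) or 3 (0.051). Tox lost the call without any of the 3 GMP fl/BRM2 arrays or GMP fl/p30 replicates 1 and 2 (adjusted p up to 0.23). It lost it also in a fit of the 6 arrays alone (0.891), over all probe sets (0.314) and with the replicate number as a block (0.171). In contrast, 12 genes were called without GMP fl/p30 replicate 3 and 283 with array weights.

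The fl/p30 genotype was then examined one stage earlier, in preGM fl/p30 against preGM +/+. These groups differed at both alleles. An effect of the p30 allele therefore cannot be told apart from that of the floxed allele, the target of the knockout. Gzmb rose by 5.23 ± 0.27 (log2 difference, n = 3 arrays per group) and Scin by 4.79 ± 0.23, followed by Zfp711 (3.14), Tox (6.29-fold), Cpa3 (5.77-fold), Olfr417, Sh2d1b1, St8sia6, Olfr248 and Clec4e. F13a1 (-5.07 ± 0.54) and the annexin gene Anxa3 (-4.01) fell, as did Cxcr2 (7.15-fold) and Ms4a6c (6.98-fold). Hp, the gene of haptoglobin, fell by 4.06, Igsf6 by 3.74, Ngp by 3.39, Abcd2 by 3.37 and the receptor kinase gene Met by 2.96, and Ly86 (-3.32) fell as well. Clec4e, Hp, Abcd2 and Ly86 lost the call with any 1 of the 6 arrays left out (adjusted p up to 0.141), Igsf6 without preGM +/+ replicate 1 or 2 or preGM fl/p30 replicate 1 or 3 (0.0625), Ngp without preGM +/+ replicate 2 (-2.74, adjusted p = 0.104) or any preGM fl/p30 array, and Met without preGM +/+ replicate 2 or preGM fl/p30 replicate 3 (0.0715).

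Of 20 monocyte and dendritic genes, 7 fell, 0 rose and 13 did not pass (12 fell adjusted over the list alone). Besides F13a1 these included Irf8 (-2.12), Flt3, the receptor of early lymphoid and dendritic progenitors (-1.79), and Csf1r, the M-CSF receptor (-2.04). Csf1r, Ly86 and Ctss lost the call with any 1 of the 6 arrays left out (Ctss at an adjusted p up to 0.155), and the count was 4 in each leave-out but that of preGM fl/p30 replicate 1, where it was 5. The list was called with the preset correlation (adjusted p = 2.14e-13) and with an estimated one (adjusted p = 0.0104). The same held for the cytokine receptors (2.48e-06 and 0.0104), of which Csf1r, Ifngr2 and the IL-6 receptor gene Il6ra fell and 12 of 15 did not pass (5 fell adjusted over the list alone). Csf1r and Ifngr2 lost the call with any 1 of the 6 arrays left out (adjusted p up to 0.159 and 0.128), Il6ra with none. Secondary granule genes fell in 4 of 20 cases, Ltf, Ngp, Mmp8 and Cxcr2 (10 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation), and primary granule genes in 2 of 14, Hp and Igsf6 (6 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation). Ltf lost the call without any preGM fl/p30 array (up to 0.117) and Mmp8 without preGM +/+ replicate 2 or preGM fl/p30 replicate 3 (up to 0.0573). Hoxa9 (-1.18), a homeobox gene of early progenitors, and Hoxa5, Trib1 and Flt3 fell among 20 Hoxa and leukaemia-linked genes (4 adjusted over the list alone; adjusted p = 0.145 with an estimated correlation). Hoxa5 and Trib1 lost the call when any array but preGM fl/p30 replicate 2 was left out (up to 0.0905 and 0.158). Hlf, a factor of stem and early progenitor cells, fell by 1.17.

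E2F and S phase genes were called lower as a list with 0 of 29 passing over all genes and 8 lower adjusted over the list alone (adjusted p = 0.191 with an estimated correlation), and the G2 and M phase list with 0 of 24 either way (adjusted p = 0.325 with an estimated correlation). Myc and ribosome biogenesis genes fell in 2 of 23 cases, Cad and Rcc1 (4 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation), both lost without any array but preGM fl/p30 replicate 2 (adjusted p up to 0.114 and 0.178). Interferon response genes rose in 4 of 22 cases and fell in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.268 with an estimated correlation), and Ifit3, Oas2, Usp18 and Gbp3 among them lost the call with any 1 of the 6 arrays left out (up to 0.204), when 0 or 1 rose and 0 fell. Ccl5, Lat and Bcl11b rose among 15 T and NK genes (4 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation), each losing the call in some leave-outs: Bcl11b in all 6 (up to 0.171), Ccl5 without preGM +/+ replicate 3 or preGM fl/p30 replicate 1 (up to 0.0618) and Lat without preGM +/+ replicate 2 (0.0521). None of 18 erythroid genes passed (0 also adjusted over the list alone), and the list's call (adjusted p = 0.0355) was lost with an estimated correlation (adjusted p = 0.547) and without preGM +/+ replicate 1 (0.131), preGM fl/p30 replicate 2 (0.0512) or 3 (0.0922). The B lymphoid list, with 0 of 17 genes passing, was called lower (adjusted p = 0.00969), but not with an estimated correlation (0.547), and turned higher without preGM +/+ replicate 3 (adjusted p = 0.522). Other lists called with the preset correlation and not with an estimated one were megakaryocyte (0.191), p53 targets (0.147) and C/EBP family (0.155), higher, and oxidative phosphorylation (0.547) and glycolysis and hypoxia (0.261), lower. The calls of p53 targets, T and NK and C/EBP family genes were lost without preGM fl/p30 replicate 2 (0.0512 each), T and NK also without preGM +/+ replicate 1 (0.0533), and C/EBP also without preGM fl/p30 replicate 3 (0.0904) or GMP fl/BRM2 replicate 1 (0.0543).

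Here 334 genes were called, 129 higher and 205 lower, with 2794 at an unadjusted p under 0.05 and no overlap of the arrays for 25.1% of genes (chance 10%). The count was 132, 101 and 136 without preGM +/+ replicates 1, 2 and 3, and 128 and 135 without preGM fl/p30 replicates 1 and 3. It was 1070 in a fit of the 6 arrays alone, 1167 with array weights and 173 with the fold threshold. Of 46 named calls, 21 held whichever array was left out.

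**Figure D2:**
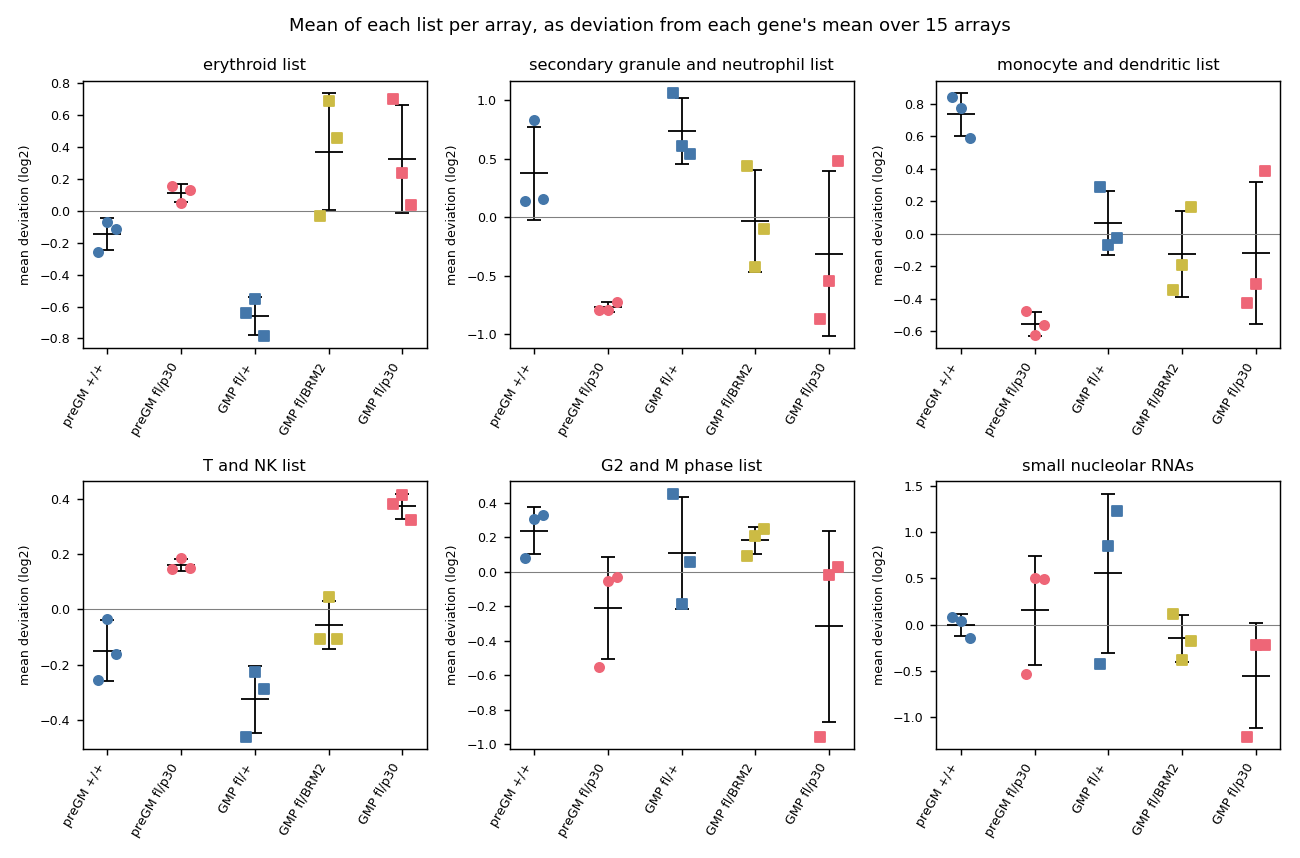
Mean deviation (log2, y axis) of 5 fixed gene lists and of the small nucleolar RNA genes from each gene's mean over 15 arrays, by group (x axis), with 1 point per array and a black line at the group mean with bars of 1 SD (n = 3). The 3 GMP fl/+ arrays lie at -0.55 or lower for the erythroid list, the 3 preGM fl/p30 arrays at -0.48 or lower for the monocyte and dendritic list, and the small nucleolar RNAs range from -0.42 to 1.23 within GMP fl/+.

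How far the comparisons shared their changes was measured across genes, which are not independent replicates. In GMPs, 349 genes were called higher and 94 lower with both p30 and BRM2, where independent lists of the same sizes would share 17.7 and 1.8, and 0 genes were called in opposite directions. These lists are not independent, as both comparisons subtract the same control arrays. That raises the overlap and lowers opposite calls by an amount that was not simulated, so the excess of shared calls cannot be judged. The log2 differences of the 2 comparisons correlated at r = 0.897 (Spearman 0.805). Both use the same control arrays, and unchanged groups simulated on shared controls gave r = 0.50 with a common spread and 0.65 with each group's own. The covariance was 0.129, against 0.0189 and 0.0338 simulated, a difference of 0.111 and 0.0956. The 3 control arrays were too few to give each comparison controls of its own with 2 arrays, so part of the excess may come from them. For p30 in the 2 stages, which share no array but share the fl/p30 animals, 88 genes rose and 45 fell in both (chance 6.0 and 2.8) and 1 gene was called in opposite directions. There r was 0.432 (Spearman 0.20) with a covariance of 0.0566, and r was 0.290 without GMP fl/+ replicate 1. Unchanged groups simulated with arrays of an animal correlated as estimated (0.304) gave r = 0.151 and a covariance of 0.0057. The preGM differences used here also include that of the floxed allele, as their control was +/+.

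The step from preGM to GMP was first described in the control groups, whose genotypes differ, so that stage and control genotype cannot be told apart. Dntt fell by 6.20 ± 0.27 (log2 difference, n = 3 arrays per group), Flt3 15.9-fold (-3.99 ± 0.28), Ctla2a and Gimap6 9.17-fold and 9.12-fold, and Myct1 by 2.95. Sgms2, a sphingomyelin synthase gene, was 13.4-fold higher, Olr1 by 3.45 and Gda by 3.37. The chromatin remodeller gene Chd7 was higher by 3.19 in its brightest probe set, by 0.54 to 3.88 in the others and by 2.09 in the mean of all, which was called too. Prg2 was 11.5-fold higher (3.52; 2.88 and 4.23 without preGM +/+ replicates 1 and 2), but without preGM +/+ replicate 1 or 3 its call was lost (adjusted p up to 0.0813). Stem and multipotent progenitor genes fell in 11 of 22 cases and rose in 0 (13 fell adjusted over the list alone), led by Meis1 (-2.43), Angpt1 (-2.38), Eya1 (-2.16) and Hlf (-1.69), with a camera adjusted p of 6.09e-10 and an adjusted p = 0.0517 with an estimated correlation (7 fell without preGM +/+ replicate 1 or 2). Hoxa and leukaemia-linked genes fell in 6 of 20 cases, Hoxa5 and Hoxa9 among them (11 adjusted over the list alone; adjusted p = 0.0517 with an estimated correlation). Interferon response genes fell in 6 of 22 cases, including Rtp4 (-1.88) and Xaf1 (-1.20) (9 adjusted over the list alone; adjusted p = 0.294 with an estimated correlation). The count was 3 without preGM +/+ replicate 1 or 3 or GMP fl/+ replicate 2, where Ifit2, Oasl2 and Trim30a lost the call (adjusted p up to 0.175), as Ifit2 did without preGM +/+ replicate 2 or GMP fl/+ replicate 3. Dntt, Blnk, Il7r and Rag2 fell among 17 B lymphoid genes (6 adjusted over the list alone; adjusted p = 0.342 with an estimated correlation). Blnk was at -2.10 (-1.48 without preGM +/+ replicate 3), and Rag2 lost the call without preGM +/+ replicate 2 or 3 or GMP fl/+ replicate 3 (up to 0.121). Of 17 mast cell, basophil and eosinophil genes 6 rose, including Hdc (1.78) and Prss34 (1.85) (6 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), and 3 without preGM +/+ replicate 1, where Mcpt8, Prg3 (both 0.051) and Prg2 lost the call. Of 6 C/EBP family genes, Cebpb, Cebpd, Cebpe and Ddit3 rose (4 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation; 0.118 with the preset one without GMP fl/+ replicate 1), Cebpe losing the call without any preGM +/+ array or GMP fl/+ replicate 2 (up to 0.0914). The gates themselves select on FcgRII, and Fcgr3 was higher by 2.98 and Fcgr2b by 1.48. Eng fell by 0.74, although only the preGM gate excluded Endoglin. Car1, Car2 and Icam4 fell among 18 erythroid genes, with Gata1 (4 adjusted over the list alone; adjusted p = 0.472 with an estimated correlation), whose call was lost with any 1 of the 6 arrays left out (up to 0.139). Other lists called with the preset correlation and not with an estimated one were primary granule (0.591), higher, and monocyte and dendritic (0.294), cholesterol synthesis (0.472), oxidative phosphorylation (0.591), Myc and ribosome biogenesis (0.591) and E2F and S phase (0.638), lower. The primary granule call was also lost without GMP fl/+ replicate 1 (0.166).

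This comparison called 2036 genes, 836 higher and 1200 lower (458 and 1542 with each array centred on its median), with 6312 at an unadjusted p under 0.05 and no overlap for 34.0% of genes (chance 10%). The count was 636, 794 and 830 without preGM +/+ replicates 1, 2 and 3, and 4686, 798 and 1289 without GMP fl/+ replicates 1, 2 and 3. It was 253 with only GMP fl/+ replicate 1, 746 in a fit of the 6 arrays alone, 4660 with array weights and 450 with the fold threshold. The housekeeping list was itself called lower (adjusted p = 0.0299; 0.472 with an estimated correlation). Its levels were 0.128, -0.293 and -0.246 in the 3 GMP fl/+ arrays, and it lost the call without GMP fl/+ replicate 2 (0.104) or 3 (0.136) or preGM +/+ replicate 2 (0.066). Differences in quality between these arrays may therefore be part of the count.

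In fl/p30 mice the same step was measured in arrays from the same 3 animals. The SEs and calls that follow ignore this pairing unless a block is named. Dntt fell 19.7-fold (log2 difference -4.30 ± 0.27), Adgrl4, an endothelial adhesion receptor gene, 7.09-fold, Flt3 6.48-fold, the T-cell receptor gene segment Trgv1 by 2.74 and Myct1 by 2.44. Papss2, an enzyme gene of sulfate activation, rose 7.65-fold, Csf2rb by 2.06 and Cma1, a mast cell chymase gene, by 1.74. Igsf6 (3.28), Anxa3 (3.19), Il6 (2.58) and Ms4a3 (2.50) were also higher, and their calls depended on single arrays. Without GMP fl/p30 replicates 1 and 3 the differences were 4.21 and 2.37 for Igsf6 and 4.02 and 2.34 for Anxa3. Igsf6 and Anxa3 lost theirs without any preGM fl/p30 array or GMP fl/p30 replicate 2 or 3 (adjusted p up to 0.183), Il6 without preGM fl/p30 replicate 2 or 3 (0.0706) and Ms4a3 without preGM fl/p30 replicate 3 (0.057). Mast cell, basophil and eosinophil genes rose in 3 of 17 cases, Cma1, Hdc and Csrp3 (7 adjusted over the list alone), with the list called also with an estimated correlation (adjusted p = 0.0123). Hdc (1.76; 1.16 without GMP fl/p30 replicate 3) lost the call without any preGM fl/p30 array or GMP fl/p30 replicate 2 and Csrp3 without preGM fl/p30 replicate 2 or 3 or GMP fl/p30 replicate 1 or 2 (up to 0.156 and 0.0824), and 5 rose without GMP fl/p30 replicate 3. Csf2rb and Csf2rb2 rose among 15 cytokine receptors (4 adjusted over the list alone; adjusted p = 0.0364 with an estimated correlation), Csf2rb2 losing the call without preGM fl/p30 replicate 3 (0.0855). Primary granule genes rose in 2 of 14 cases, Ms4a3 and Igsf6 (6 rose without GMP fl/p30 replicate 1; 9 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation), and among 22 interferon response genes Mx2 fell (9 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), which was lost without preGM fl/p30 replicate 2 or 3 or GMP fl/p30 replicate 1 or 3 (up to 0.146). Fcgr3 was higher by 2.36. In all, 128 genes were called, 71 higher and 57 lower, with 2475 at an unadjusted p under 0.05, and no overlap for 17.2% of genes (chance 10%). Pairing the arrays by animal as a random block gave 681 genes, and 172 with the animals as fixed terms. The call of the monocyte and dendritic list (adjusted p = 0.0269) was lost with that random block (0.07), with an estimated correlation (0.395) and without preGM fl/p30 replicate 2 (0.0855) or GMP fl/p30 replicate 3 (0.402). Other lists called with the preset correlation and not with an estimated one were stem and multipotent progenitor (0.157), Hoxa and leukaemia-linked (0.0509) and B lymphoid genes (0.55), lower, and secondary granule (0.55), erythroid (0.678) and cholesterol synthesis genes (0.613), higher. These last 3 lost the call without preGM fl/p30 replicate 1 (0.0749, 0.0678 and 0.157). Secondary granule genes lost it also without preGM fl/p30 replicate 2 (0.0579) or GMP fl/p30 replicate 3 (0.842). Erythroid genes lost it also without preGM fl/p30 replicate 2 (0.0855), GMP fl/p30 replicate 1 (0.39) or GMP fl/+ replicate 1 (0.0612), and cholesterol synthesis without preGM fl/p30 replicate 3 (0.0549) or GMP fl/p30 replicate 2 (0.108) or 3 (0.228). The count without the block was 80, 61 and 26 without preGM fl/p30 replicates 1, 2 and 3, 29 in a fit of the 6 arrays alone, 70 over all probe sets, 76 with the fold threshold and 1948 with array weights.

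Whether p30 acted differently in the 2 stages was tested as the difference between its effects (GMP minus preGM), in which the controls' genotypes also differ. The main fit did not pair the arrays of the fl/p30 animals. P2rx7, which encodes an ATP-gated ion channel, was the 1 gene called (1.65 ± 0.21, adjusted p = 0.0269), with 2616 genes at an unadjusted p under 0.05. It rose by 0.98 in GMP fl/p30 (adjusted p = 0.00132) and fell by 0.68 in preGM fl/p30 (adjusted p = 0.0337). A rise of 0.88 ± 0.15 was also seen in GMP fl/BRM2 against GMP fl/+ (adjusted p = 0.0054), so it is not particular to p30. The call of P2rx7 in the interaction was lost without any of the 3 preGM +/+ arrays, preGM fl/p30 replicate 1 or 3, GMP fl/+ replicate 3 or GMP fl/p30 replicate 2 (adjusted p up to 0.147). Mmp8 (2.98 ± 0.54), Cx3cr1 (2.57 ± 0.42), Angpt1 (2.26 ± 0.37), Il7r (2.04 ± 0.39) and Prss34 (-1.77 ± 0.29) did not pass, at adjusted p of 0.072 to 0.0746. Camera called 11 lists with 0 members passing over all genes, led by the monocyte and dendritic list (mean difference 1.11, 7 of 20 genes higher adjusted over the list alone, adjusted p = 1.64e-06), and 0 lists with an estimated correlation (adjusted p = 0.11 or more). The count was 1482 without GMP fl/+ replicate 1, 117 without GMP fl/p30 replicate 3, 4 without preGM fl/p30 replicate 2, 3 without GMP fl/+ replicate 2, and 0 without any preGM +/+ array, preGM fl/p30 replicate 1, GMP fl/+ replicate 3 or GMP fl/p30 replicate 2. It was 76 with the fl/p30 animals paired as a random block, 25 with them as fixed terms, 4 in a fit of the 12 arrays alone, 1991 with array weights and 0 over all probe sets.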

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

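The tests of other splits, paired or not, and of preGM cells in the GMP gate were chosen after the result was seen. The difference between the p30 effects was tested as an interaction, and the results below are those whose effects differed between GMPs and preGMs in it. P2rx7 differed by 1.65 (GMP minus preGM), rising in GMP fl/p30 and falling in preGM fl/p30. It rose in GMP fl/BRM2 too (0.88). Camera called 11 gene lists, with 0 members passing in limma's test over all genes (2616 of all genes had an unadjusted p under 0.05). Their mean differences were 1.108 for the monocyte and dendritic list, 0.726 for erythroid, 0.664 for B lymphoid, 0.65 for cholesterol synthesis, 0.541 for cytokine receptors, 0.473 for stem and multipotent progenitor, 0.388 for T and NK, 0.381 for oxidative phosphorylation, 0.314 for glycolysis and hypoxia, 0.247 for the Hoxa and leukaemia-linked list and 0.193 for E2F and S phase. With an estimated correlation, 0 of these 11 were called (adjusted p of 0.11 to 0.646).

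Single arrays decided some of these list calls. Without preGM +/+ replicate 3 the B lymphoid call was lost (adjusted p = 0.408), and without GMP fl/+ replicate 1 those of T and NK (0.145) and Hoxa genes (0.258). The Hoxa call was also lost without preGM +/+ replicate 1 (0.0528) or GMP fl/p30 replicate 1 (0.0573) or 2 (0.0748). That of E2F and S phase was lost without preGM fl/p30 replicate 1 (0.198), GMP fl/+ replicate 2 (0.0507) or GMP fl/p30 replicate 3 (0.585), and that of glycolysis without GMP fl/+ replicate 2 (0.0523) or GMP fl/p30 replicate 3 (0.139). Of 100 splits of the arrays within each stage, the real one included, 10 gave at least the 1 gene called, so chance is not excluded for that count. The highest other split called 1475 genes. The 100 were drawn from splits that include swapping the labels of 1 stage alone. That swap turns the contrast into the sum of the p30 effects, so a high count need not point to a structure among the samples. These fits ignore that the fl/p30 arrays of the 2 stages share their animals, and with the animals as a random block the real split called 76 genes. Of the 28 splits that keep both arrays of each such animal on the same side, 1, the real one, called as many with that block. The highest other called 1 gene. That share is under 0.05, but the other splits put fl/p30 and control arrays in the same group, which widens the spread and lowers their counts. The correlation of the arrays was also estimated from the real groups, so chance is not excluded for the paired count either. The GMP control was fl/+ and the preGM control +/+, so a difference between the controls' genotypes is confounded with the difference between stages and was not tested.

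Cells of the earlier stage in the GMP gate of fl/p30 mice were weighed as a technical explanation for preGM genes that were higher in GMP fl/p30 than in GMP fl/+. Each of 83 genes that stood above GMP fl/+ in preGM fl/p30 gives the share of preGM cells that its level would need, with a median of 71.5% and quartiles of 43.4% and 92.4% (their ratio was 2.13, against 1.26 to 1.54 in 100 simulations of a single share, too near to decide alone). Of 68 such genes abundant in preGM fl/p30 (a level of at least 8), 40 had GMP fl/p30 arrays on both sides of the median share, but 5 needed at most 34.6% in each array and 5 over 100%. Dntt stood at 6.11 where the median share would bring 9.94, and Dntt, Flt3, Myct1 and Trgv1 needed 3.3%, -8%, 3.7% and 6.7%. Those over 100% included Gzmb and Scin, which were lower in preGM +/+ (5.09 and 5.84) than in GMP fl/+ (7.30 and 6.13). They rose with p30 and are not genes of the preGM stage in the controls, so the median share may partly measure the p30 response. Of the Fc receptor genes, Fcgr3 changed by 0.00 (95% interval from -0.43 to 0.43), against -1.24 at the median share, which allows at most 32.1%. Fcgr2b changed by -1.07 (-1.72 to -0.42), against -1.13 at that share, which needs at least 33.6%. These 2 bounds lie close and take the preGM and GMP fl/+ levels as exact, so the 2 genes cannot be said to disagree. Fcgr3 argues against the median share. Dntt, Flt3, Myct1 and Trgv1 argue against cells like the sorted preGMs, at 1 share, as the whole source. A share as small as Dntt allows (2.5% to 4.4% over the arrays), preGM cells low in those 4 genes, and immature cells that carry the receptor through a changed differentiation in the mutant stay open and were not tested.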

How the results depend on the processing

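The setting with only GMP fl/+ replicate 1 as GMP control was chosen after the data, and its counts, were seen; it assumes that a lone array varies like the other groups. Counts follow the order GMP fl/p30 and GMP fl/BRM2 against GMP fl/+, preGM fl/p30 against +/+, GMP fl/p30 against fl/BRM2, the step to GMP in fl/p30, the same step in controls, and the interaction, whose main counts were 1209, 505, 334, 1, 128, 2036 and 1. With arrays left out in turn they ranged from 537 to 3078, 134 to 2218, 101 to 223, 0 to 12, 26 to 120, 636 to 4686 and 0 to 1482, the highest against GMP fl/+ and in the interaction being those without GMP fl/+ replicate 1. Array weights gave 4063, 2187, 1167, 283, 1948, 4660 and 1991, of which 1185, 502, 334, 1, 128, 1980 and 1 were among the main calls. In the weighted fit GMP fl/p30 rested mainly on replicate 2 (weight 6.02, against 0.33 and 0.79 for replicates 1 and 3). Only the arrays compared gave 172, 131, 1070, 0, 29, 746 and 4, and the fold threshold 482, 274, 173, 1, 76, 450 and 1. With only the arrays compared, preGM fl/p30 thus had more calls than either GMP mutant, the reverse of the main order. The main counts therefore do not rank the stages. All probe sets as separate tests gave 277 for BRM2, 1.7e+02 for preGMs (62 higher and 107 lower), 0 between the mutants, 70 for the fl/p30 step and 0 in the interaction. GMP fl/+ replicate 1 alone gave 311 and 113 for the 2 mutants and 253 for the control step. Between the mutants, variance trend, median centring and quantile normalization gave 2 each and the number block 0 (also 0 in the interaction). The fl/p30 animals as a random block gave 681 for the fl/p30 step and 76 in the interaction, and with fixed terms 25 in the latter. Of 175 list tests 82 were called, 72 to 87 with arrays left out, 6 with an estimated correlation and 36 by fry. The correlation of p30 and BRM2 stayed at 0.8494 to 0.9259 and that of p30 in the 2 stages at 0.2904 to 0.5282 with arrays left out. Other counts stayed within 1.5 times. Named calls were lost in 459 of 1530 values with arrays left out, in 102 of 254 with only the arrays compared, in 88 of 254 over all probe sets and in 115 of 185 with only GMP fl/+ replicate 1 as GMP control; none of the settings turned the direction of a named called gene. The direction of 2 list calls turned, for B lymphoid genes in preGMs without preGM +/+ replicate 3 and for E2F genes between the mutants without GMP fl/p30 replicate 1 (adjusted p = 0.522 and 0.07). Fewer tests or arrays, or a stricter threshold, make part of these changes by construction; otherwise the cause was not tested. Small changes are limited by 3 arrays per group and by signal near the array background.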

Other observations

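The tests of cell types and of other splits and the simulations of held-out controls were chosen after the result was seen, and the tests with held-out controls before their results but after the counts without single arrays. Of all genes, 64 were called higher and 22 lower in each of GMP fl/p30, GMP fl/BRM2 and preGM fl/p30 against its control, and the genes named here were chosen after their values were seen. For preGM fl/p30 that control was +/+, so its differences include that of the floxed allele. Besides Scin and Gzmb, the shared rises included Tox (4.10, 1.85 and 2.65 in that order), Prkcq (3.65, 3.09 and 1.47), Cpa3 (3.09, 3.00 and 2.53), the leukotriene enzyme gene Alox5 (3.01, 2.68 and 1.61), the thrombin receptor gene F2r (2.97, 2.60 and 1.53), Cd96 (2.60, 1.87 and 1.13), Lag3 (1.97, 1.53 and 1.56) and Zbtb16 (1.57, 1.13 and 1.17). Shared falls included F13a1 (-3.02, -2.60 and -5.07), Hdc (-2.21, -1.90 and -2.19), Irf8 (-1.72, -1.44 and -2.12), the heparanase gene Hpse (-1.56, -1.48 and -2.63), Hlf (-0.64, -0.71 and -1.17), and the IL-6 receptor genes Il6st (-1.96, -1.31 and -2.08) and Il6ra (-0.55, -0.64 and -1.14). In the 2 GMP comparisons Hlf kept its call only without GMP fl/+ replicate 1 (adjusted p up to 0.0993 and 0.185 without the others), and Il6ra lost it without GMP fl/+ replicate 3, GMP fl/p30 replicate 1 or 2, or GMP fl/BRM2 replicate 2 or 3 (up to 0.123 and 0.139). For BRM2, Irf8 and F13a1 lost it without GMP fl/+ replicate 2 or GMP fl/BRM2 replicate 2 and Hdc without the latter (up to 0.119, 0.11 and 0.0814).

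T or NK cells among the sorted progenitors would raise such genes as Gzmb, Lag3 and Cd96 together with the rest of their abundant transcripts. The highest median of the T and NK list in the 3 comparisons was 0.551 (SD of members 0.691), against rises of Gzmb of 4.63, 4.51 and 5.23. Gzmb was picked as 1 of the largest rises. The list also holds genes near the background, such as Cd3g (4.17 in GMP fl/+), whose rise may be understated, so this gap decides little. As 86.7%, 66.7% and 73.3% of the list lay above 0, a contribution of T or NK cells may remain. For mast cells or basophils, 58.8%, 58.8% and 64.7% of their list lay above 0, so members went both ways: Cpa3 rose and Hdc fell in each comparison. That share decides nothing, and a contribution of such cells may remain. A direct or indirect effect of the mutant C/EBPα within the progenitors, the biological explanation the design gives, stays open and was not tested further.

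The number of genes called against GMP fl/+ changed with its arrays, so the controls were held out in turn. The 3078 genes called without GMP fl/+ replicate 1 kept 0.231 of their log2 difference (0.185 to 0.307 over the GMP fl/p30 arrays) when measured against that array, with 70.5% in the same direction. As the GMP fl/p30 arrays enter both differences, 100 simulations of unchanged groups kept 0.40 (0.373 to 0.437) with 72.2%. This longer list kept less than any of them. The simulations gave all groups 1 gene-wise spread and no difference in quality between the GMP fl/+ arrays. A share of 0.25 had been set for calls made by replicates 2 and 3, with their high small nucleolar RNAs. It lies within the range over the GMP fl/p30 arrays and below what unchanged groups kept. It therefore cannot decide, and that explanation stays open. The 311 genes called with GMP fl/+ replicate 1 as only control kept 0.837 (0.811 to 0.915) against replicates 2 and 3, with 94.5% in the same direction, where unchanged groups kept at most 0.304 (0.313 for a single array) with at most 84.2%, which argues against replicate 1 having made most of those calls. Differences between the animals themselves were not tested.

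With 3 arrays in each group there are 10 splits, too few for a share under 0.05. The real split and the highest other one called 1209 and 417 genes for GMP fl/p30, 505 and 1 for GMP fl/BRM2, and 334 and 0 for preGM fl/p30, each against its control. They called 128 and 0 genes for the step to GMP in fl/p30, and 2036 and 1 for that step in the controls. Between GMP fl/p30 and GMP fl/BRM2 the real split called 1 gene and the highest other one 24, with 2 of the 10 calling at least 1. What sets apart the arrays in the splits with 24 and 417 calls was not tested. Array weights from limma were lowest for GMP fl/+ replicates 1 and 2 (0.30 and 0.33), GMP fl/p30 replicate 1 (0.33) and preGM fl/p30 replicate 1 (0.43), and highest for GMP fl/p30 replicate 2 (6.02).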
